A study of Homo sapiens with 6 samples.

How the data were processed

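RNA sequencing was done on BeWo cells, a human trophoblast line derived from a choriocarcinoma, transduced stably with lentivirus. Cells of one arm carried an empty vector (OE-NC, n = 3) and those of the other overexpressed RNF126 (OE-RNF126, n = 3). The series describes the 3 libraries of each arm as independent experiments, and does not say whether these were separate transductions. Per the labels' protocols, total RNA was isolated with TRIzol and libraries were made with the VAHTS Universal V6 kit. Per the submitters' processing notes, fastp, HISAT2, HTSeq and R 3.2.0 were used with the GRCh38.p13 build, named with no role or order. The strand setting, the gene annotation and the counting options were not given in the sources used here. Reads of overlapping and antisense genes, and of near-identical gene copies, therefore cannot be assigned with certainty.

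The authors deposited whole-number counts per gene symbol for 15731 genes, each with at least 1 count in 1 library, with 1 column per library and no normalization. They also deposited FPKM values for the same genes and libraries. The deposited FPKM values were recomputed as the count divided by a whole-number gene length and by the sum of the count column, and differed from that by a relative 5.5e-07 at most. FPKM was thus scaled by library totals with no further factor. Mitochondrially encoded mRNAs were not among the listed genes, so that list was not analysed here.

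Counts were the measure for all main results. Library totals were 33370951 to 35468777 counts. Genes were kept by the filterByExpr defaults of edgeR 4.0.16 in R 4.3.3, which left 12538 genes. Libraries were scaled by the TMM method, with factors of 0.9854 to 1.0147. OE-RNF126 was compared with OE-NC by edgeR's quasi-likelihood F-test with the arm as the single term, two-sided, over all 6 libraries. P-values were adjusted by the Benjamini-Hochberg method over the tested genes, and the threshold was an adjusted p under 0.05. The common biological coefficient of variation was 0.0522. Standard errors were the log2 coefficient divided by the square root of F. Expression levels are given as CPM (normalised counts scaled to a common library size) on the TMM scale, as mean ± SD of 3 libraries. Principal components were computed on log2 CPM with a prior count of 2.

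Before the data were examined, 29 gene lists with 795 entries (764 different genes) were fixed, of which 28 had at least 5 tested members. They covered the unfolded protein response and protein quality control, the actomyosin cytoskeleton, trophoblast states, placental transport and growth, other stress and signalling programmes, other cell types and RNA quality. Each was tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 28 lists. Camera compares a list with all other tested genes. Its estimated-correlation form was run beside it, and 30 genes were held by more than 1 list. A further 5 lists were written after the data were seen and appear only in the closing section, with adjustment over those 5 lists.

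Genes named in the text followed a rule also fixed before the data were examined. RNF126, MYH9 and MYH10 were always named. Genes with an adjusted p under 0.05, non-overlapping CPM between arms and a mean of at least 50 counts in the higher arm were eligible by size, the 12 with the largest log2 fold change each way, and by p, the 4 with the smallest p each way. From each list the 4 tested members with the smallest p were eligible. Genes outside that rule are marked as chosen after their values were seen. Gene positions were taken from GENCODE 29 on the GRCh38 primary assembly, which gave a position for 12263 of the 12538 tested genes by symbol.

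The whole procedure was tested on simulated counts for OE-RNF126 against OE-NC, with 12399 genes tested. Counts were drawn from the OE-NC means, the trended dispersion and the real library sizes. Of 50 genes changed at each size, 40% were called at 1.2-fold, 88% at 1.5-fold, 94% at 2-fold and 100% at 4-fold. Few of the 12537 simulated genes were thus changed, whereas 21.9% of tested genes were called in the real data. The adjustment of p depends on that share, so these percentages do not give the sensitivity of the real comparison. Of the genes simulated without a change, 6 were called, and with no gene changed 0 were called. The 95% intervals held the simulated change for 95.2% of genes. Of 200 random lists without a change, 0 had a camera p under 0.05. The simulated genes were drawn independently and the list members at random. These lists therefore do not test false calls among genes that vary together. In the real data the estimated correlation reached 0.557, for ribosomal protein genes, against the preset 0.01.

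Alternatives planned before the data were examined were other scalings (DESeq2 size factors, upper quartile, library size only), other low-count filters, the replicate number as a block, leaving out each library, DESeq2 1.42.0, limma-voom, limma-trend on log2 of the deposited FPKM plus 1 or 0.1, other thresholds, camera with an estimated correlation, and the rotation test fry. Added after seeing the data were an offset for GC content and exon length per library, removal of RNF126 from the table, and lists without shared members. GC content was available for 12472 of the tested genes.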

Results

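The transcriptome of BeWo trophoblast cells was measured in 3 libraries of cells with an empty lentiviral vector (OE-NC) and 3 libraries of cells overexpressing RNF126 (OE-RNF126). BeWo cells come from a gestational choriocarcinoma and are widely used as a model of villous trophoblast. RNF126 is a RING-type E3 ubiquitin ligase that acts with the chaperone BAG6 in the quality control of misfolded and mislocalised proteins. The series concerns RNF126, stress of the endoplasmic reticulum (ER) in fetal growth restriction, and turnover of the non-muscle myosin heavy chains encoded by MYH9 and MYH10. The comparison therefore asked which transcripts differed between OE-RNF126 and OE-NC cells. Total counts were 34314038, 35104276 and 35468777 in OE-NC and 33370951, 34854931 and 34773717 in OE-RNF126, and 14152 to 14340 genes had a count in each library. The libraries separated by arm on the first principal component, which held 32% of the variance. No 2 libraries agreed within sampling noise, since the chi-square per degree of freedom was 4.147 to 5.539 within arms and 24.24 to 31.29 between them.

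RNF126 mRNA was 62.3-fold higher in OE-RNF126 cells. It rose from 56.7 ± 2.33 CPM (SD, n = 3) to 3530 ± 71.1 CPM, with a log2 fold change of 5.96 ± 0.027 (SE) and an edgeR adjusted p of 4.61e-68. RNF126 took 0.00548% to 0.0059% of all counts in the OE-NC libraries and 0.342% to 0.355% in the OE-RNF126 libraries. The exact 95% binomial intervals over all 3 libraries ran from 0.00523% to 0.00616% and from 0.340% to 0.357%, and cover counting error only. The gene lies on chromosome 19 from 647526 to 663277 on the minus strand (ENSG00000070423.17). The counts do not separate the transgene from the endogenous gene.

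MYH10 mRNA was slightly lower, and MYH9 mRNA did not pass the test. MYH9 (chromosome 22, 36281277 to 36388067) had 1889 ± 24.9 CPM in OE-NC and 1920 ± 46.5 CPM in OE-RNF126 cells (n = 3 each). Its log2 fold change of 0.02 ± 0.020 (SE) did not pass the threshold (edgeR adjusted p = 0.459), and the 95% interval was -0.02 to 0.06. MYH10 (chromosome 17, 8474205 to 8630761) was lower, at 521.9 ± 3.30 CPM against 488 ± 15.6 CPM. Its log2 fold change was -0.10 ± 0.025 (SE), a ratio of 0.935, with an edgeR adjusted p of 0.00319. The sign of the MYH9 fold change rests on the scale, since scaling by library size alone moved the median of all genes to -0.04 and MYH9 with it to -0.01. MYH9 passed the threshold with an offset for GC content and exon length that was added after the data were seen (0.08). These values describe mRNA, and the amount of either protein was not measured here.

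**Figure D1:**
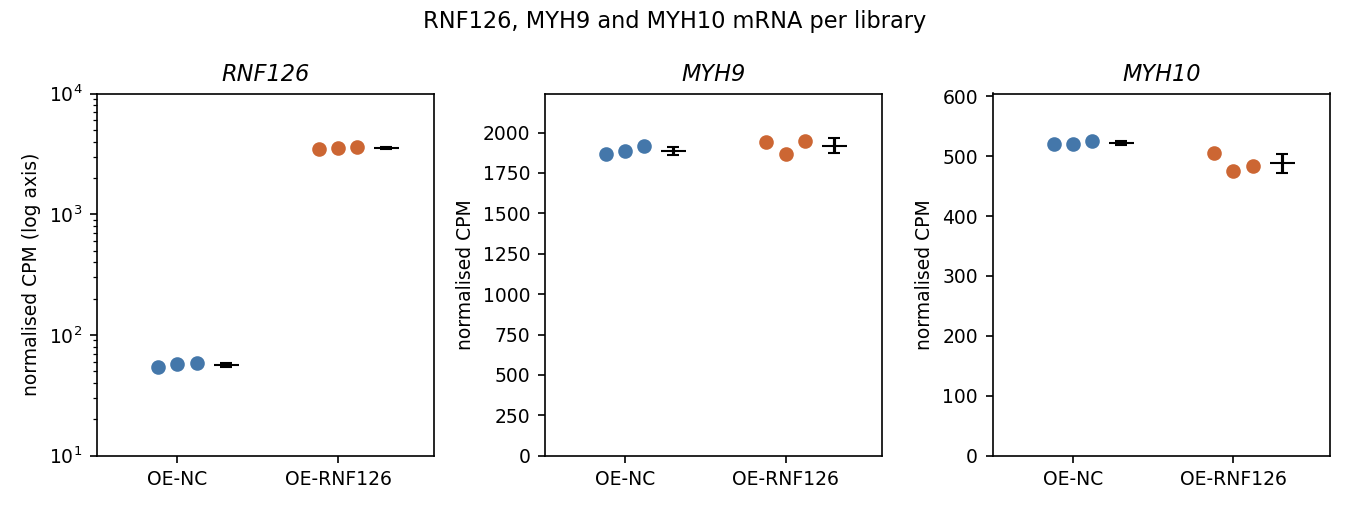
Normalised CPM of RNF126 (log axis), MYH9 and MYH10 (axes from 0) in each of the 3 OE-NC (blue) and 3 OE-RNF126 (orange) libraries; the horizontal mark and bar beside each group are the mean and SD of 3 libraries. RNF126 rose 62.3-fold, MYH9 values of both arms overlapped, and MYH10 was lower in the OE-RNF126 libraries, at a ratio of 0.935.

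Many transcripts shifted by small amounts. Of 12538 genes tested, 1438 were higher and 1312 lower in OE-RNF126 cells, together 21.9%. The median size of the log2 fold change among these 2750 genes was 0.198. At least 2-fold changes were found for 38 of the higher and 13 of the lower genes. CPM values of the arms did not overlap for 2605 of the 2750 genes and for 34.7% of tested genes, where chance gives 10%. With library size alone as the scale the split was 930 higher and 1853 lower, and on the deposited FPKM, scaled in the same way, it was 644 higher and 1361 lower with a pseudocount of 1.

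After RNF126, the higher genes with the smallest p were HSPA5, UBC and PLIN2. HSPA5, the main HSP70 chaperone of the ER lumen (chromosome 9, 125234853 to 125241330), went from 2347 ± 23.7 to 3882 ± 130.1 CPM, a log2 fold change of 0.73 ± 0.019 (SE) with an edgeR adjusted p of 8.5e-33. The polyubiquitin gene UBC rose by a log2 fold change of 0.91 ± 0.026, and PLIN2, which encodes a lipid droplet coat protein, by 0.66 ± 0.022. Larger rises were found for less abundant transcripts. The immediate-early transcription factor gene EGR1 rose from 3.16 ± 0.218 to 13.7 ± 0.757 CPM (log2 fold change 2.11 ± 0.14), and JUN from 0.442 ± 0.125 to 1.66 ± 0.281 CPM (1.90 ± 0.41). The lower genes with the smallest p were ISM2, the atypical cadherin gene FAT2, the angiopoietin gene ANGPT4 and the metalloprotease gene ADAM19. Their log2 fold changes were -0.47 ± 0.028, -0.48 ± 0.029, -0.53 ± 0.038 and -0.34 ± 0.024. STAT4, a signal transducer of cytokine receptors, fell from 4.73 ± 0.166 to 2.40 ± 0.292 CPM (-0.98 ± 0.21).

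**Figure D2:**
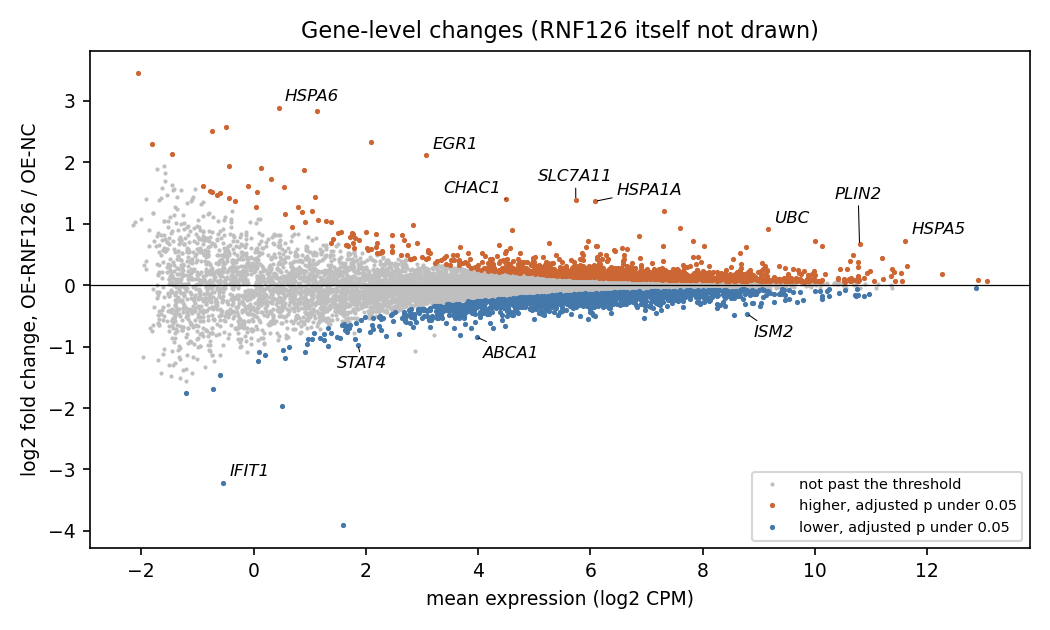
Log2 fold change of OE-RNF126 over OE-NC (vertical axis) against mean log2 CPM (horizontal axis) for each tested gene except RNF126; genes with an edgeR adjusted p under 0.05 are coloured by direction. The 1438 higher and 1312 lower genes lay mostly close to 0, with HSPA5 at 0.73 among the abundant and EGR1 at 2.11 among the less abundant genes.

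Genes listed under the unfolded protein response, the set of programmes induced by misfolded protein in the ER, rose together. The activity of PERK, IRE1 and ATF6 was not measured, so the lists do not show which branch, if any, acted. Among ER chaperones and ATF6 targets, 19 of 20 members were higher and 0 lower, with a median log2 fold change of 0.21 (camera adjusted p = 1.89e-38). Besides HSPA5, these included the ER HSP90 gene HSP90B1 (log2 fold change 0.45 ± 0.018 SE), HERPUD1 (0.71 ± 0.030) and the ER chaperone gene HYOU1 (0.31 ± 0.024). Among targets of the IRE1-XBP1 branch, 15 of 23 were higher and 0 lower (median 0.18, camera adjusted p = 3.81e-09). The ER co-chaperone gene DNAJB9 rose by 0.52 ± 0.052, the COPII coat gene SEC31A by 0.34 ± 0.029 and the translocon genes SEC61A1 and SSR3 by 0.17 ± 0.023 and 0.20 ± 0.031. Among targets of the PERK-ATF4-CHOP branch, 27 of 31 were higher and 0 lower (median 0.24, camera adjusted p = 4.06e-52). DDIT4, an inhibitor of mTORC1 signalling, rose from 96.0 ± 11.8 to 222 ± 8.68 CPM (1.21 ± 0.045), and the cystine transporter gene SLC7A11 from 29.6 ± 3.08 to 77.5 ± 3.00 CPM (1.39 ± 0.058). Asparagine synthetase ASNS rose by 0.80 ± 0.043, the secreted factor STC2 by 0.53 ± 0.030 and the glutathione-degrading enzyme CHAC1 by 1.40 ± 0.084. Genes of ER-associated degradation, which returns misfolded proteins to the cytosol, were higher in 9 of 23 and lower in 0 (median 0.09, camera adjusted p = 1.04e-06). They included the segregase gene VCP (0.26 ± 0.024), SEL1L (0.32 ± 0.031) and EDEM1 (0.19 ± 0.030).

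The stress regulators themselves were chosen after their values were seen. DDIT3, which encodes CHOP, rose from 17.1 ± 2.06 to 31.6 ± 1.77 CPM (log2 fold change 0.89 ± 0.083 SE, edgeR adjusted p = 4.76e-12). Smaller rises were found for ATF4 (0.13 ± 0.026), XBP1 (0.19 ± 0.030) and ERN1, which encodes IRE1 (0.24 ± 0.070). ATF6 had a log2 fold change of 0.05 ± 0.044 and did not pass the threshold (edgeR adjusted p = 0.5). The ERN1 call was lost in all 3 FPKM settings (0.15 with a pseudocount of 1) and the ATF4 call in 2 of them (0.10). Counts adjusted over the list alone were 19, 15, 28 and 10 higher for the chaperone, IRE1-XBP1, PERK-ATF4-CHOP and degradation lists. With an estimated correlation, the camera adjusted p was 0.0244 for each of the first 3 lists and 0.0264 for the degradation list, so these calls held.

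**Figure D3:**
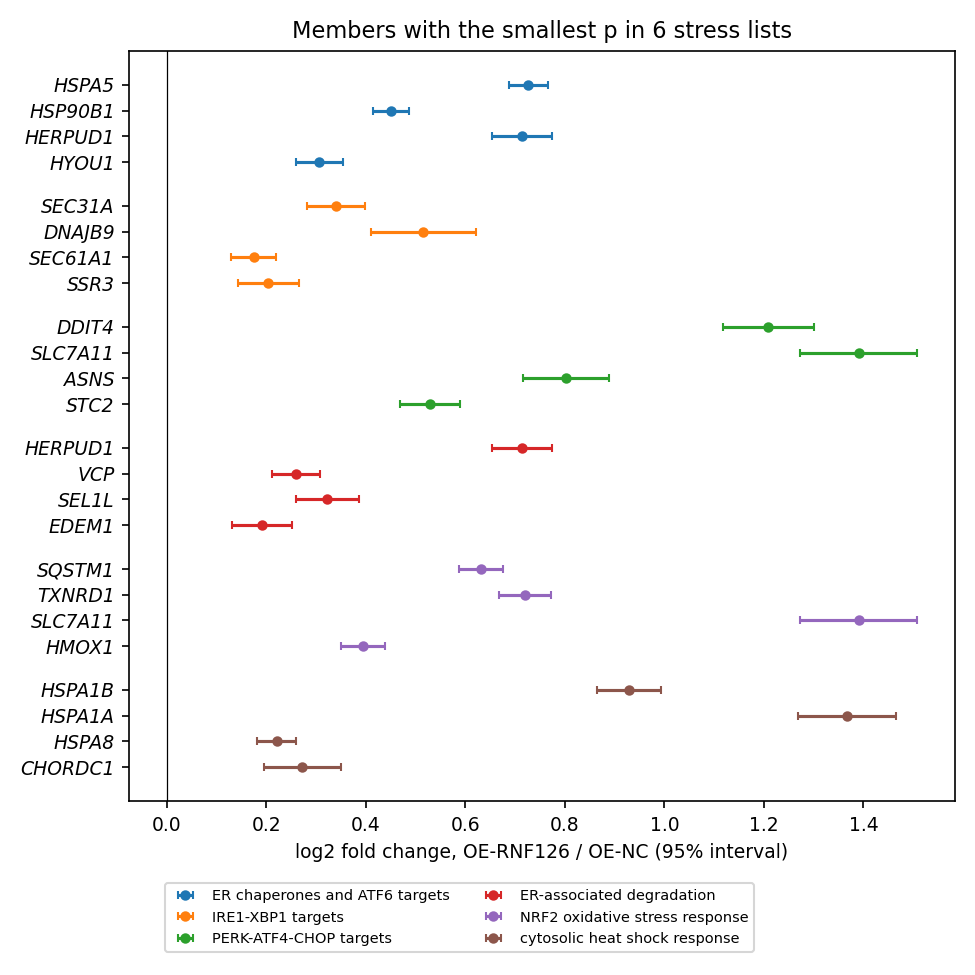
Log2 fold change of OE-RNF126 over OE-NC (horizontal axis) with its 95% interval for the 4 members with the smallest p in each of 6 stress lists, coloured by list; a gene held by 2 lists is drawn in both. The points lie between 0.17 for SEC61A1 and 1.39 for SLC7A11, and each interval lies above 0.

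Oxidative stress and heat shock genes moved in the same direction. Of 22 NRF2 oxidative stress genes, 15 were higher and 1 lower (median 0.30, camera adjusted p = 2.98e-29, and 0.0264 as the adjusted p with an estimated correlation). The autophagy receptor gene SQSTM1 rose from 883 ± 22.8 to 1367 ± 25.1 CPM (log2 fold change 0.63 ± 0.022 SE), thioredoxin reductase TXNRD1 by 0.72 ± 0.026 and heme oxygenase HMOX1 by 0.39 ± 0.022. The member that fell was AKR1B10 (-0.19 ± 0.043), named after its value was seen. Of 14 genes listed under the cytosolic heat shock response, 10 were higher and 1 lower (median 0.10, camera adjusted p = 1.28e-12, but adjusted p = 0.0526 with an estimated correlation). The near-identical genes HSPA1A and HSPA1B cannot be told apart by every read, and their summed CPM rose 2.05-fold, from 171 ± 6.56 to 352 ± 4.26. The constitutive HSPA8 rose by 0.22 ± 0.020. The strictly inducible HSPA6, which the list does not hold, rose from 0.312 ± 0.153 to 2.33 ± 0.764 CPM (2.89 ± 0.42). The genes that follow were named after their values were seen. HSPA4L fell (-0.29 ± 0.054), and BAG3 did not pass (0.04 ± 0.050, edgeR adjusted p = 0.661). The higher members included DNAJB1 (0.13 ± 0.039), HSPD1 (0.10 ± 0.021) and HSPE1 (0.15 ± 0.049). HSPD1 and HSPE1 encode mitochondrial chaperones, so the list is not purely cytosolic. Adjusted over the list alone, 16 NRF2 genes were higher and 1 lower, and 10 heat shock genes higher and 1 lower. With library size alone as the scale, 6 heat shock genes were higher.

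Proteasome subunit genes were higher in 21 of 31 and lower in 0, or 22 and 0 adjusted over the list alone, by a median of 0.10. The regulatory particle genes PSMD14 and PSMC6 rose by log2 fold changes of 0.21 ± 0.033 and 0.23 ± 0.036 (SE). The camera adjusted p was 7.98e-07, but the adjusted p was 0.202 with an estimated correlation, and 11 subunit genes were higher with library size alone as the scale. Of 17 genes of BAG6 quality control and reported RNF126 partners, 4 were higher and 1 lower, also adjusted over the list alone, and the list did not pass camera (adjusted p = 0.166) but passed fry (0.00396), which does not compare a list with other genes. BAG6 itself rose by 0.14 ± 0.027, its cofactor gene SGTA by 0.17 ± 0.040 and the cell cycle inhibitor gene CDKN1A by 0.30 ± 0.026.

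Genes of p53 signalling and cell death were partly higher. Of 26 p53 target genes, 11 were higher and 3 lower, or 12 and 3 adjusted over the list alone (median 0.05, camera adjusted p = 4.21e-06, and 0.0462 as the adjusted p with an estimated correlation). GDF15, a secreted factor also listed under syncytiotrophoblast, rose by a log2 fold change of 0.63 ± 0.026 (SE), the stress gene SESN2 by 0.63 ± 0.036 and MDM2, which encodes the ligase of p53, by 0.26 ± 0.023. The members that fell were TP53 (-0.26 ± 0.042), the DNA polymerase gene POLH (-0.20 ± 0.042) and SPATA18 (-0.26 ± 0.073), all 3 named after their values were seen. Without members held by other lists, the p53 list had a camera adjusted p of 0.475. Of 32 apoptosis regulators, 7 were higher and 0 lower, or 9 and 2 adjusted over the list alone. The list did not pass in the main analysis (camera adjusted p = 0.0709), but passed with no low-count filter (0.0222), with the replicate number as a block (0.0419), without OE-RNF126 replicate 3 (0.0453), with RNF126 removed (0.0363) and with fry (0.0259). The BH3-only genes PMAIP1 and BBC3 rose by 0.56 ± 0.085 and 0.52 ± 0.081, the survival gene MCL1 by 0.18 ± 0.025 and the death receptor gene TNFRSF10B by 0.19 ± 0.031. Of 37 cell cycle genes, 7 were higher and 4 lower, or 8 and 4 adjusted over the list alone (camera adjusted p = 0.831). With library size alone as the scale, 4 cell cycle genes were higher and 7 lower, and 7 apoptosis regulators higher and 4 lower. The mitotic cyclin gene CCNB1 fell by 0.18 on the log2 scale and the replication licensing gene CDT1 rose by 0.20.

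Actomyosin genes changed in both directions. Of 34 genes of non-muscle myosin II and the actin cytoskeleton, 9 were higher and 14 lower, or 11 and 17 adjusted over the list alone. The list did not pass (camera adjusted p = 0.484), and its median of -0.03 and mean of 0.06 differed in sign. The mean includes CCN2 (2.58 ± 0.55 SE), named after its value was seen and near the lower limit of the counts at 0.188 CPM in OE-NC. The matricellular gene CCN1 rose by a log2 fold change of 0.40 ± 0.034 (SE) and the actin gene ACTG1 by 0.20 ± 0.019. The tropomyosin gene TPM1 (-0.23 ± 0.022) and the myosin light chain gene MYL9 (-0.36 ± 0.039) fell. Of 23 epithelial-mesenchymal and matrix genes, 1 was higher and 8 lower, or 3 and 11 adjusted over the list alone (median -0.08). The lower members included E-cadherin CDH1 (-0.18 ± 0.022), the laminin genes LAMC1 (-0.16 ± 0.021) and LAMB1 (-0.15 ± 0.023) and the integrin gene ITGB4 (-0.17 ± 0.027). The higher member was the laminin gene LAMB3, at 1.21 ± 0.186 and 2.47 ± 0.248 CPM, named after its value was seen. The camera adjusted p of 0.0158 rose to an adjusted p of 0.189 with an estimated correlation, and was 0.0784 with the offset for GC content and exon length. With library size alone as the scale, 6 actomyosin genes were higher and 17 lower, and 1 epithelial-mesenchymal and matrix gene higher and 13 lower.

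Trophoblast genes changed in both directions. Of 30 syncytiotrophoblast differentiation and hormone genes, 9 were higher and 6 lower, or 10 and 6 adjusted over the list alone (median 0.19, camera adjusted p = 0.00201). The adjusted p was 0.0588 with an estimated correlation and 0.0685 without members shared with other lists. Besides GDF15, placental growth factor PGF (log2 fold change 0.25 ± 0.022 SE), the transcription factor gene OVOL1 (0.39 ± 0.044) and the estradiol-forming enzyme gene HSD17B1 (0.22 ± 0.026) rose. The remaining called members, CGA, GCM1 and ERVW-1 among them, were named after their values were seen. LEP (0.65), CYP19A1 (0.25), CGB8 (0.69) and HSD3B1 (0.52) were higher. GH2 (-0.39), CSH1 (-0.49), CSH2 (-0.40) and SDC1 (-0.11) were lower. The alpha subunit of chorionic gonadotropin, CGA, was higher (0.15 ± 0.039), and the fusion regulator GCM1 (-0.12 ± 0.033) and syncytin-1, ERVW-1 (-0.11 ± 0.031), were lower. The CGA call was lost without OE-NC replicate 2 (0.10) and on FPKM (0.12), and the ERVW-1 call without OE-NC replicate 2 (-0.08) or OE-RNF126 replicate 2 (-0.07). Of 20 villous cytotrophoblast and progenitor markers, 3 were higher and 9 lower, or 3 and 10 adjusted over the list alone (camera adjusted p = 0.127). The keratin genes KRT18 and KRT8 rose by 0.26 and 0.19, and the imprinted gene PEG10 fell by 0.26 on the log2 scale. Of 19 extravillous trophoblast markers, 5 were higher and 6 lower, or 8 and 8 adjusted over the list alone. That list did not pass camera (adjusted p = 0.213) but passed fry (0.0148), and its median (0.00) and mean (0.20) lay above 0 while camera's direction was down. The mean includes MMP9 (2.29 ± 0.80), named after its value was seen and near the lower limit of the counts at 0.075 CPM in OE-NC. SERPINE1 rose by 0.18, and NOTCH2 (-0.26) and the integrin gene ITGA1 (-0.22) fell. With library size alone as the scale, 2 cytotrophoblast markers were higher and 10 lower (camera adjusted p = 0.0342, past the threshold), and 3 extravillous markers higher and 8 lower. The cytotrophoblast list also passed with no low-count filter (0.0271) and without OE-NC replicate 1 (0.0369).

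Transport and metabolic lists did not pass as groups in the main analysis, apart from ribosomal protein genes. Of 23 placental nutrient transporter genes, 8 were higher and 4 lower (camera adjusted p = 0.168). The glucose transporter gene SLC2A3 rose from 1362 ± 47.3 to 1905 ± 48.1 CPM (log2 fold change 0.48 ± 0.022 SE), and the cholesterol efflux gene ABCA1 fell from 20.1 ± 0.763 to 11.2 ± 1.51 CPM (-0.84 ± 0.10). Of 12 growth factor and imprinted placental genes, 1 was higher and 3 lower (camera adjusted p = 0.131), with the imprinted gene PEG3 at -0.29 ± 0.025. Of 32 hypoxia and glycolysis genes, 9 were higher and 5 lower (camera adjusted p = 0.168), and NDRG1 rose by 0.69 ± 0.063. Of 25 cholesterol genes, 2 were higher and 6 lower (camera adjusted p = 0.446). HMGCS1 rose by 0.22 ± 0.028, and SQLE (-0.18 ± 0.044) and INSIG1 (-0.16 ± 0.039) fell. Of 36 nuclear-encoded genes of oxidative phosphorylation, 7 were higher and 1 lower (camera adjusted p = 0.0709), with the ATP synthase gene ATP5F1B at 0.11 ± 0.022. That list passed with no low-count filter (0.0187), with the replicate number as a block (0.0386), without OE-RNF126 replicate 1 (0.0227), with RNF126 removed (0.0359) and with fry (0.0364). With fry the transporter (0.00404), growth factor (0.0136) and hypoxia (0.0309) lists passed too. Adjusted over the list alone, the counts were the same for the transporter, growth factor and oxidative phosphorylation lists, 10 and 6 for hypoxia and 2 and 7 for cholesterol. With library size alone as the scale, 5 transporter genes were higher and 6 lower, 8 hypoxia genes higher and 8 lower, 3 oxidative phosphorylation genes higher and 1 lower, 1 cholesterol gene higher and 7 lower, and 1 growth factor gene higher and 4 lower.

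Ribosomal protein genes were higher in 28 of 46 and lower in 0, or 33 and 0 adjusted over the list alone, by a median log2 fold change of 0.07. RPL5 had 0.12 ± 0.020 (SE). The camera adjusted p was 1.64e-05, but the adjusted p was 0.436 with an estimated correlation, and 8 members were higher with library size alone as the scale.

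Interferon-stimulated genes were lower. Of 23 members, 0 were higher and 11 lower, also adjusted over the list alone (median -0.28, camera adjusted p = 0.000608, but adjusted p = 0.0526 with an estimated correlation). The signal transducer gene STAT1 fell from 217.1 ± 4.0 to 194 ± 2.15 CPM (log2 fold change -0.16 ± 0.031 SE), the tetherin gene BST2 by 0.20 and IFI6 by 0.19 on the log2 scale. IFIT1 was near the lower limit of the counts, with 1.12 ± 0.247 CPM in OE-NC and 0.117 ± 0.116 CPM in OE-RNF126 (-3.21 ± 0.61). IFI27 fell from 2.49 ± 0.854 to 1.17 ± 0.139 CPM (-1.09 ± 0.31), a call that was lost without OE-NC replicate 1 (-0.86). Of 14 NF-kB and inflammatory genes, 1 was higher and 0 lower, and 0 passed adjusted over the list alone (camera adjusted p = 0.929). The list's median was 0.03 while camera's direction was down, and with library size alone as the scale 1 member was higher and 1 lower. The higher member, RELB (0.57 ± 0.19), lost its call without OE-NC replicate 3 (0.45), OE-RNF126 replicate 1 (0.54) or OE-RNF126 replicate 3 (0.51).

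No list of markers of other cell types passed camera upward. Of 10 tested fibroblast and stromal markers, 0 were higher and 2 lower, also adjusted over the list alone. These 2 were the microfibril gene MFAP5 (log2 fold change -0.37 ± 0.027 SE), at 344 ± 4.80 CPM in OE-NC, and the collagen gene COL6A3 (-0.38 ± 0.047). The list passed downward (camera adjusted p = 0.0321, but adjusted p = 0.179 with an estimated correlation). Of 5 endothelial and blood cell markers, 0 were higher and 1, VE-cadherin CDH5, lower (-0.22 ± 0.025), also adjusted over the list alone (camera adjusted p = 0.176, fry adjusted p = 0.0341). Of 6 markers of the embryonic kidney line used for lentivirus packaging, LIN28B was higher (0.24 ± 0.022) and BEX3 lower (-0.22 ± 0.031), also adjusted over the list alone (camera adjusted p = 0.655). In OE-NC and OE-RNF126, CDH5 had 799 ± 31.5 and 686 ± 20.8 CPM and LIN28B 819 ± 13.4 and 966 ± 21.5 CPM, abundant in both arms. Some other members were near the lower limit of the counts, such as AIF1 (0.273 CPM in OE-NC) and HOXD9 (0.863 CPM in OE-NC). These lists are therefore a weak measure of other cells. Of 10 replication-dependent histone genes, a measure of RNA selection, 0 were higher and 0 lower, also adjusted over the list alone (camera adjusted p = 0.914). The 4 members with the smallest p had only 0.124 to 0.760 CPM in OE-NC, with an SE of 0.49 to 0.90 on the log2 scale. The absence of calls therefore does not show that RNA selection was equal between arms.

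**Figure D4:**
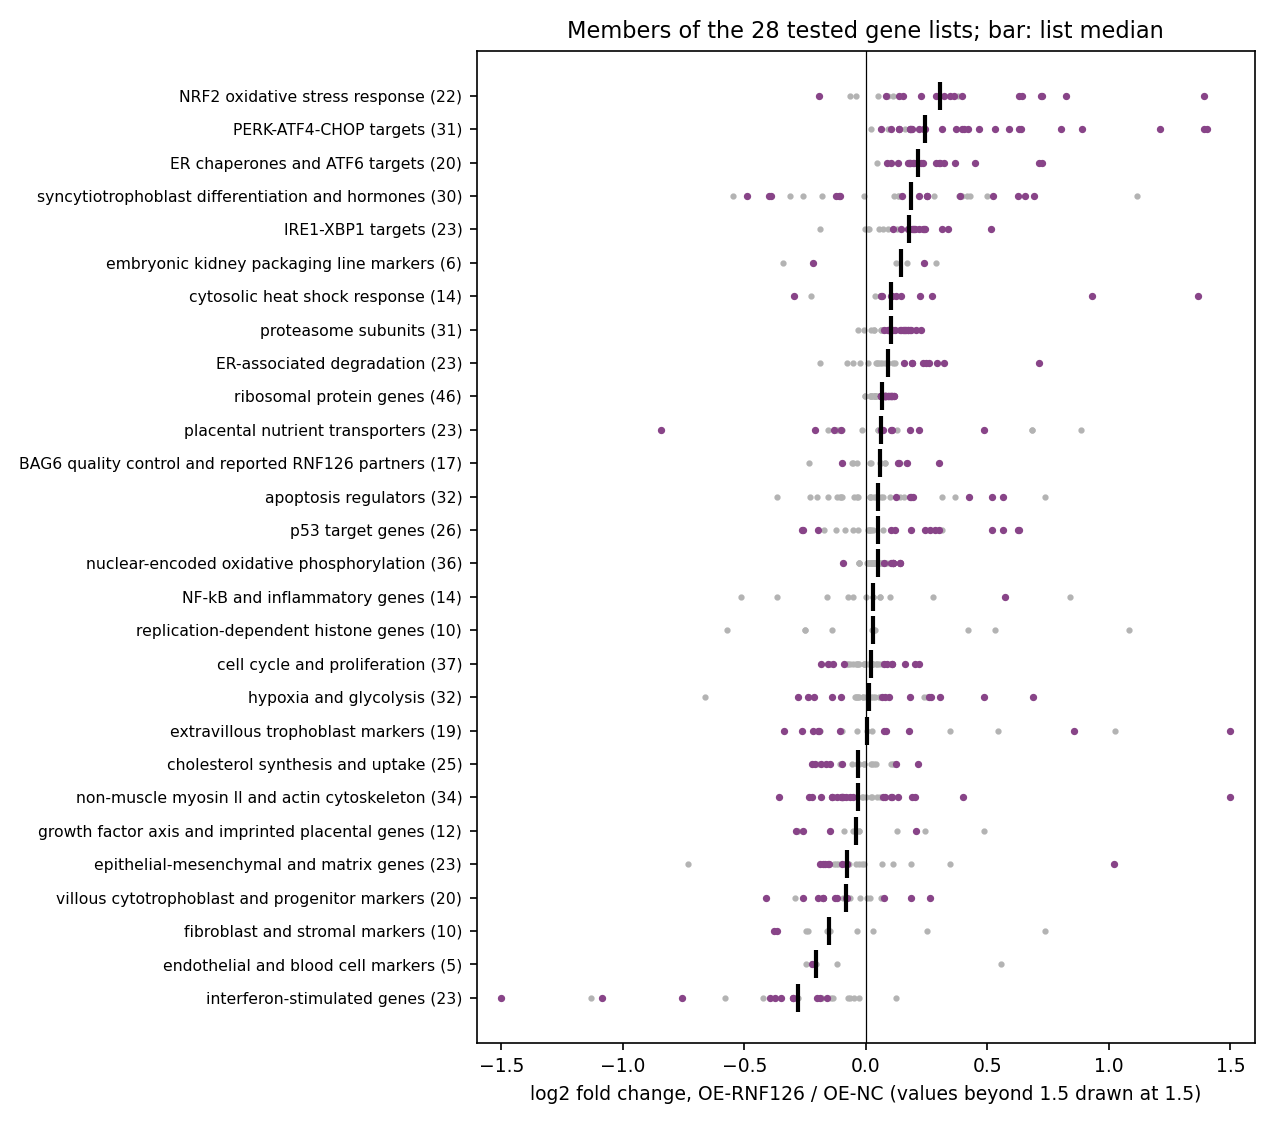
Log2 fold change of OE-RNF126 over OE-NC (horizontal axis) for the tested members of each of 28 lists (rows, with the number of members), purple where the edgeR adjusted p was under 0.05; the bar marks the list median, 3 points beyond 1.5 in size are drawn at that limit on their own side of 0, and RNF126 is left out. NRF2 genes had the highest median, 0.30, and interferon-stimulated genes the lowest, -0.28.

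Of the 28 lists, 13 passed camera, 10 upward and 3 downward, and 6 of them, all upward, also passed with an estimated correlation. Where edgeR called 0 members of a list in a direction, 0 were also found there at an unadjusted p under 0.05, by DESeq2 and by limma-voom, with 2 exceptions. At an unadjusted p under 0.05, 4 apoptosis regulators and 2 NF-kB genes were lower, and limma-voom called 1 NF-kB gene lower. The libraries do not separate an effect of RNF126 from other differences between the 2 transduced populations, since no other line or vector was compared.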

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

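RNF126 and MYH10 kept their direction and call under each alternative scaling, low-count filter, tool, block and left-out library, with ranges of 5.93 to 5.98 for RNF126 and -0.12 to -0.08 for MYH10 when single libraries were left out. Thresholds on the size of the change were not applied to single genes, and MYH10, at a ratio of 0.935, lies below both. The reversed sign of MYH9 with library size alone (-0.0117) and on log2 FPKM with a pseudocount of 1, of 0.1 and with a mean FPKM of at least 1 (-0.0119, -0.012 and -0.0119) is 1 shift of all genes and not 4 findings, since these settings share a scale. With the GC and length offset, added after the data were seen, MYH9 passed at 0.0772. Why it passed there was not tested. Genes called higher numbered 930 with library size alone, where the median of all genes was -0.04, and 644, 655 and 681 in the FPKM settings, which share that scaling. Fewer passed stricter thresholds by construction, with 926 higher and 816 lower at an adjusted p under 0.01, 38 and 13 at 2-fold, and 74 and 38 against a 1.2-fold change with glmTreat. The other count settings stayed within 1.5 times of the main counts, with 1116 to 1345 higher and 1018 to 1210 lower when single libraries were left out. Of the 2750 calls, 2494 were shared by DESeq2 and 2311 by the GC and length offset.

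The lists past the threshold numbered 6 with an estimated correlation and 21 with fry, which does not compare a list with other genes, and 13 to 14 without single libraries. For the named genes other than RNF126, MYH9 and MYH10, 1993 of 2008 values of called genes under alternatives kept direction and call and 15 lost the call. Of 234 values of called lists, 224 kept the call and 10 lost it, and of 270 values of lists not called, 19 gained it. Apoptosis regulators and oxidative phosphorylation gained it in 5 settings each and villous cytotrophoblast markers in 3. Over the 18 alternatives the adjusted p of lists that lost a call ran from 4.22e-10 to 0.202 for the proteasome, 1.3e-15 to 0.0526 for heat shock, 7.87e-08 to 0.436 for ribosomal proteins, 0.000112 to 0.0526 for interferon-stimulated genes, 0.00042 to 0.0685 for syncytiotrophoblast, 0.00303 to 0.189 for epithelial-mesenchymal and matrix genes, 0.00404 to 0.179 for fibroblast markers and 1.88e-07 to 0.475 for p53 targets. Deviations of libraries with the same replicate number correlated at 0.04, 0.01 and -0.02, and not every library correlated best with its own number. These values gave no sign that the numbers pair libraries. They cannot exclude pairing, since all tested genes weighed alike and counting noise of rare transcripts lowers such correlations. With the replicate number as a block, 1526 genes were higher, 1387 lower and 15 lists passed. With 3 libraries per arm at the real library sizes, the simulation recovered 40% of 1.2-fold changes, and depth was not varied. Only 50 genes were changed at each size there, so this is not the sensitivity of the real comparison.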

Other observations

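The 5 gene lists below, the GC and length offset, the removal of RNF126, the comparisons within and without the window and the count of called genes per chromosome were chosen after the data were seen, and the window, zinc finger and tRNA synthetase tests followed from patterns found in the data.

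Genes that charge tRNAs in the cytosol rose. Of 20 cytosolic aminoacyl-tRNA synthetase genes, 12 were higher and 0 lower (median log2 fold change 0.15, camera adjusted p = 1.81e-12, and 0.0164 as the adjusted p with an estimated correlation). The examples CARS1 (0.57 ± 0.047 SE), TARS1 (0.36 ± 0.026) and EPRS1 (0.35 ± 0.027) were chosen after their values were seen. Of 17 mitochondrial synthetase genes, 1 was higher and 1 lower (median -0.03, camera adjusted p = 0.518). The medians differed by 0.18 (one-sided permutation p over genes 0.00019), and by 0.15 without the 3 genes that the PERK-ATF4-CHOP list also holds (p = 0.00068). Genes are not independent replicates. The split is consistent with the hypothesis that ATF4, known to act on cytosolic synthetase genes, was more active in OE-RNF126 cells, which was not measured directly.

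Of 20 immediate-early genes, 12 were higher and 0 lower (median 0.31, camera adjusted p = 5.54e-11, and 0.0138 as the adjusted p with an estimated correlation). Besides EGR1 and JUN they included ATF3 (0.59 ± 0.044 SE), IER2 (0.45 ± 0.037) and FOSL1 (0.53 ± 0.075), chosen after their values were seen. Fixed lists already held 3 of the higher members, ATF3 (PERK-ATF4-CHOP) and CCN1 and CCN2 (actomyosin). The immediate-early list was not tested without them. Of 11 MHC class I and antigen presentation genes, 0 were higher and 4 lower (camera adjusted p = 0.00824, but adjusted p = 0.0701 with an estimated correlation). These were TAP1 (-0.25 ± 0.028), TAP2 (-0.20 ± 0.030), TAPBP (-0.21 ± 0.035) and B2M (-0.11 ± 0.026). Of 23 autophagy and lysosome genes, 5 were higher and 4 lower (camera adjusted p = 0.176).

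The 6 stress lists of ER chaperones, IRE1-XBP1, PERK-ATF4-CHOP, ER-associated degradation, NRF2 and heat shock had 126 tested members, of which 89 were higher and 2 lower, with a median log2 fold change of 0.185. Fold changes correlated weakly with GC content across genes (Spearman -0.14). With an offset for GC content and exon length, 6 of the 6 lists still passed camera at the preset correlation and the median was 0.19, which argues against that bias as the whole source. The estimated correlation was not run with the offset. Without the offset, 5 of the 6 lists passed with it. Leaving RNF126, at most 0.355% of counts, out of the table left the median of these lists at 0.185, so that test alone decides nothing about its share of counts. Of the 28 lists, 15 then passed, apoptosis regulators (camera adjusted p = 0.0363) and oxidative phosphorylation (0.0359) among them. Counts taken by RNF126 lower the share of other genes. With library size alone as the scale, the medians of the 6 lists were still 0.055 to 0.269. These values argue against that share as the source of the rise. An effect of RNF126 on protein quality control, a difference that arose between the transduced populations, and a difference in culture state at harvest stay open.

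The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05. The real split alone (1 of the 10) called as many as 2750 genes or 13 lists, and the other splits called 0 genes (edgeR, DESeq2 and limma-voom, with at most 381 at an unadjusted p under 0.05) and at most 11 lists, or 0 lists with an estimated correlation where the real split had 6. Each other split puts libraries of both arms in each group, so the difference between arms adds to the spread within groups. Calls of 0 there were therefore likely beforehand and do not measure chance. Camera with a preset correlation called the ER chaperone and PERK-ATF4-CHOP lists in 9 of the 9 other splits and the IRE1-XBP1, proteasome and NRF2 lists in 6 each. It called the interferon-stimulated list in 4, ER-associated degradation and ribosomal proteins in 3 each, and heat shock in 2. Syncytiotrophoblast and p53 lists were called in 1 each, and the epithelial-mesenchymal and fibroblast lists in 0. Camera at that setting is therefore not specific to the real split for most of these lists. It also called lists that the real split did not, which were oxidative phosphorylation and villous cytotrophoblast in 2 each, and apoptosis and cholesterol in 1 each. Splits that mix the arms still hold 2 libraries of one arm against 1, and whether this or a preset correlation that is too low gave these calls was not tested.

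Of the 23 interferon-stimulated genes, 8 had a mean under 100 counts, so the other 15 were tested alone. They passed camera downward (p = 0.000825, or p = 0.0234 with an estimated correlation), 9 were called lower and 14 lay below 0, with a median of -0.20. Noise in a few rare transcripts was therefore not the source of the whole pattern. A different response to the vector and an effect of RNF126 stay open, since the design has no comparison that bears on either.

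Small shifts of many genes could come from copy number changes in the transduced cells. Called genes went both ways on each of chromosomes 1 to 22 and X, with at least 12 in the rarer direction on any of them, and chromosome medians lay between -0.03 and 0.02, which argues against whole-chromosome changes as the source of most calls. The window of 50 neighbouring genes with the largest median lay on chromosome 19 from 35995199 to 38832005, at a size of 0.132 (median -0.13), with 2 genes higher and 4 lower. Of 1000 shuffles of gene order, 16 held a window as large, and a loss of 1 copy of 3 would give -0.58. Zinc finger genes were counted only by symbols of ZNF and a number, so any with other symbols fell among the other genes. These ZNF genes made up 25 of the 50 (median -0.19). The other 25 genes of the window had a median of -0.065, against -0.015 for other genes on chromosome 19 (ZNF genes against the others in the window, two-sided permutation p over genes 0.057). ZNF genes on the other chromosomes had a median of -0.001, against -0.08 on chromosome 19 (difference -0.08, two-sided permutation p over genes 0.00052, or -0.07 and 0.0055 without the window's genes, which were picked as the lowest). As genes are not independent replicates, these permutation p-values do not measure variation between libraries. The median of -0.001 on the other chromosomes argues against a fall of all ZNF genes as a class. The 2 medians set for that explanation and for a copy number change nevertheless fell between their bounds. A copy number change in part of the cells stays open. So does a change confined to ZNF genes of chromosome 19, which was not predicted beforehand.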
